A study of Homo sapiens with 6 samples.

How the data were processed

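The series holds 6 two-colour spotted oligonucleotide arrays of primary human keratinocytes, in 1 group of DKK1-treated over untreated cells. Per the file headers, the scanner images were quantified in GenePix and exported from the authors' array database with Cy3 as channel A and Cy5 as channel B. Per the file headers, the deposited intensity of each channel is the mean spot intensity minus the median local background, spots flagged bad or not found were left out, wells printed more than once in an array were reduced to the strongest, and control features were excluded, although 182 wells of random negative-control sequence and 3 wells of mixed oligonucleotides remained in the table. The deposited log2 ratios were centred by the authors on the 50th percentile of each array, per the file headers. Set against the signals, each equalled log2 of Cy5 over Cy3 minus 1 constant on arrays 1 to 5 and log2 of Cy3 over Cy5 plus 1 constant on array 6, within 0.01. Their medians over all wells were -0.22, -0.14, 0.07, 0.01, 0.04 and -0.11 on arrays 1 to 6, so the set of spots on which they were centred stays unknown. The deposited series matrix held the same ratios in 18271 of 18271 wells of each array. Software versions are not given in the sources used here.

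Signals were taken as deposited, since they were already background-corrected, and the log2 ratio of Cy5 over Cy3 was normalized within each array by loess on the mean log2 signal (span 0.3, 4 iterations) in limma 3.58.1 with R 4.3.3. Control wells and wells of Y-linked genes were left out before the curve was drawn. Wells of one oligonucleotide were averaged, which gave 17852 probes. Gene names came from the platform table, where 15091 wells had 1 symbol, 60 several and 3120 none. Symbols were updated through Entrez IDs in a RefSeq table of assembly GRCh38.p14 for 15072 wells. A further 1668 wells without a symbol there were named from the gene column of the deposited table, and 184 wells whose sources named different genes were left unnamed. Coordinates are those of the deposited table (hgB36).

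The design fixed before the data were examined entered all 6 arrays as separate replicates. Arrays 1 to 4 agreed as scans of 1 slide do, so their mean entered as 1 replicate, and the 6-array fit is given as an alternative. A probe was tested if it was measured on at least 4 arrays and 2 slides. The mean ratio was tested against 0 with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over the 8908 probes. Errors are SDs over slides and intervals are 95% limits from limma. With 3 slides an exact sign-flip test of 1 gene cannot give a p below 0.25, so no such test was made. The median 95% half-width of a probe was 0.69 on the log2 scale.

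The 27 gene lists were fixed in advance and tested with camera (preset inter-gene correlation 0.01, lists of at least 3 genes, genes measured on all 3 slides), with fry and an estimated correlation beside it. A gene was represented by the probe measured on most arrays, then by the one with the highest mean rank of signal. The rank replaced the mean signal that the design named, since scans differed in brightness. The rule for named genes took, in each direction, the 12 with the largest change past the threshold, on at least 5 arrays and with 1 sign on all, and where fewer passed up to 6 further genes of smallest p. It added every measured gene of the study's own list, and for each list up to 4 members past the threshold or else the 2 of smallest p. No gene passed, so all named genes are given as values. The text leaves out 2 of the 66 genes so chosen, which stay in the counts.

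The fit was tested on simulated data with the real missing values, with 200 of the 8908 probes changed in each of 5 runs. Errors were normal, with variances drawn from the distribution that limma fitted to the real data. They were independent between slides and probes, which real errors need not be, so the shares called hold for that model only. It called 60.8% of probes changed by 2 on the log2 scale, 24.8% of those changed by 1.5, 1.6% of those changed by 1 and 0% of those changed by 1.5-fold. Alternatives covered centring, scaling, the deposited ratios, filters on dim or missing probes, the variance model, array weights, each replicate left out, thresholds and list tests. Normexp background correction was not run, since the signals came already corrected, with no separate backgrounds. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.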

Results

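Messenger RNA of primary human keratinocytes, the main cells of the epidermis, was compared after 2 h at 37 C with or without 50 ng/ml of recombinant DKK1, a secreted antagonist of Wnt signalling. Each of the 6 two-colour oligonucleotide arrays held treated RNA labelled with Cy5 and untreated RNA labelled with Cy3, per the labels, so each array gave a ratio of treated over untreated cells. The arrays formed a single group, and nothing in the labels said whether they came from separate cultures. The p-values measure the spread between these hybridisations only. Between 10148 and 12985 of the 18271 wells carried a value on an array. The median Cy5 signal ran from 42 on array 1 to 2376 on array 6, and the number of arrays limits the precision of every value. Each sign below follows the labels, which put treated RNA in Cy5 throughout, whereas the header of the deposited table marks array 6 as reversed and gives its ratio as Cy3 over Cy5. The direction of array 6 is therefore not settled, no other dye swap was labelled, and a dye effect of a probe cannot be separated from the treatment.

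Arrays 1 to 4 differed from each other by far less than from arrays 5 and 6. Within the 6 pairs among arrays 1 to 4 the log2 signals correlated at r = 0.980 to 0.989 across wells, and single-channel signals of bright wells differed with an SD of 0.10 to 0.29 on the log2 scale. In the 9 other pairs r was 0.338 to 0.636 and that SD was 1.04 to 1.82. The wells without a value also coincided within arrays 1 to 4 (r = 0.723 to 0.751) and hardly elsewhere (r = -0.034 to 0.207). Arrays 1 to 4 were therefore counted as 4 scans of 1 hybridised slide (slide A) and averaged, which with array 5 (slide B) and array 6 (slide C) left 3 slides. That they are scans of 1 slide was inferred from these values and is not stated by the labels. The only comparison was with arrays 5 and 6, so 4 separate hybridisations are not excluded. These correlations are across wells of an array, and wells are not independent replicates. Whether every well of slide A holds the oligonucleotide listed for it also stays open, as described below, which limits each value of slide A.

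**Figure D1:**
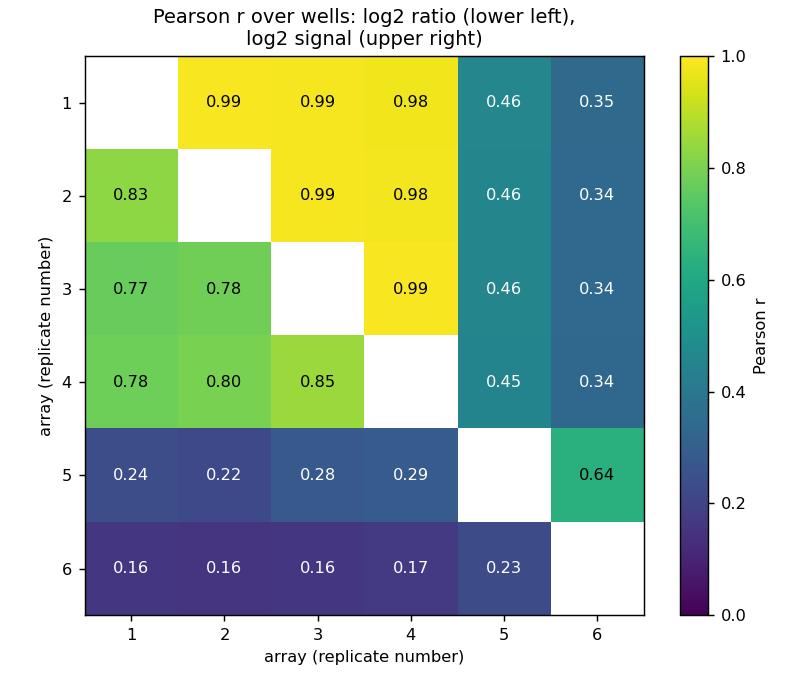
Pearson r (colour and number, no unit) between the 6 arrays, numbered by replicate on both axes, for the loess-normalized log2 ratio below the diagonal and for the mean log2 signal above it. Ratios of arrays 1 to 4 correlated at 0.77 to 0.85 with each other, and at 0.16 to 0.29 in the pairs that involve array 5 or 6.

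The comparison asked which keratinocyte transcripts differ after 2 h of DKK1. The genes with the smallest p and one sign on every array were LILRA4 (log2 ratio 1.63 ± 0.47, SD, n = 3 slides), GLTPD2 (1.38 ± 0.08), CRP (1.25 ± 0.38), AGBL3 (1.35 ± 0.63), SENP6 (1.83 ± 1.27) and ZNF230 (1.20 ± 0.39) on the higher side. SENP6 encodes a SUMO protease and CRP the acute-phase C-reactive protein. On the lower side they were UBASH3A (-1.24 ± 0.19), LYAR (-1.37 ± 0.56), ARPIN (-1.35 ± 0.57), TIPARP (-1.23 ± 0.37) and ATF3 (-1.19 ± 0.35), each on 3 slides, and LOC283075 (-1.54 ± 0.23, n = 2 slides). The SD over slides leaves out the spread of scans, which on slide A ran from -0.16 to -2.22 for UBASH3A and from 0.95 to 3.03 for AGBL3. ATF3 is a stress-induced transcription factor, TIPARP a target of the aryl hydrocarbon receptor and ARPIN an inhibitor of the Arp2/3 complex. None of these 12 genes passed the test (limma, adjusted p = 0.376 for each), so they are given as values. By mean rank of signal those on the higher side lay between 19.0% (GLTPD2) and 50.4% (SENP6) of probes. Those on the lower side lay between 29.1% (UBASH3A) and 55.5% (ATF3). Control wells of random sequence that had a value exceeded the median gene probe in 30.3% to 43.7% of cases on arrays 1 to 5 (2.13% on array 6). They leaned to Cy5 on every array (median log2 ratio 0.45 to 0.83), and the part of that lean in these values was not tested. The 11 of these 12 genes measured on array 6 cannot keep one sign with it turned, since they were chosen for one sign as labelled. A fall in their size is built in by the same rule, and SENP6 was then at 0.25, LILRA4 at 0.77, GLTPD2 at 0.52, LYAR at -0.33 and UBASH3A at -0.38.

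Over all 8908 probes tested, 0 were higher and 0 lower in the DKK1 channel at an adjusted p under 0.05 in limma. At an unadjusted p under 0.05 there were 433 higher and 694 lower probes, 12.7% of those tested against 5% by chance, and the ordinary one-sample test gave 0 and 0 after adjustment and 381 and 327 before it (7.95%). With an intensity trend and robust variance the unadjusted counts were 170 and 184 (3.97%), so neither the excess over chance nor the lean to lower values held in that fit. Of the 5606 probes measured on 3 slides, 2233 (39.8%) had one sign on all of them, 1261 higher and 972 lower, against 25% by chance. With array 6 turned 1444 (25.8%) did, 631 higher and 813 lower, so the excess over 3 slides rests on the labelled direction of array 6. Sharing between slides A and B does not involve array 6, and these had the same sign for 63.6% of 7264 probes. Turning array 6 moved 57 of the 66 genes chosen by the naming rule by over 1.5 times, changed the sign of 12 of them and lowered the counts at an unadjusted p under 0.05 to 203 and 188. Most of these genes were chosen for a small p in the labelled direction, which favours such moves.

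**Figure D2:**
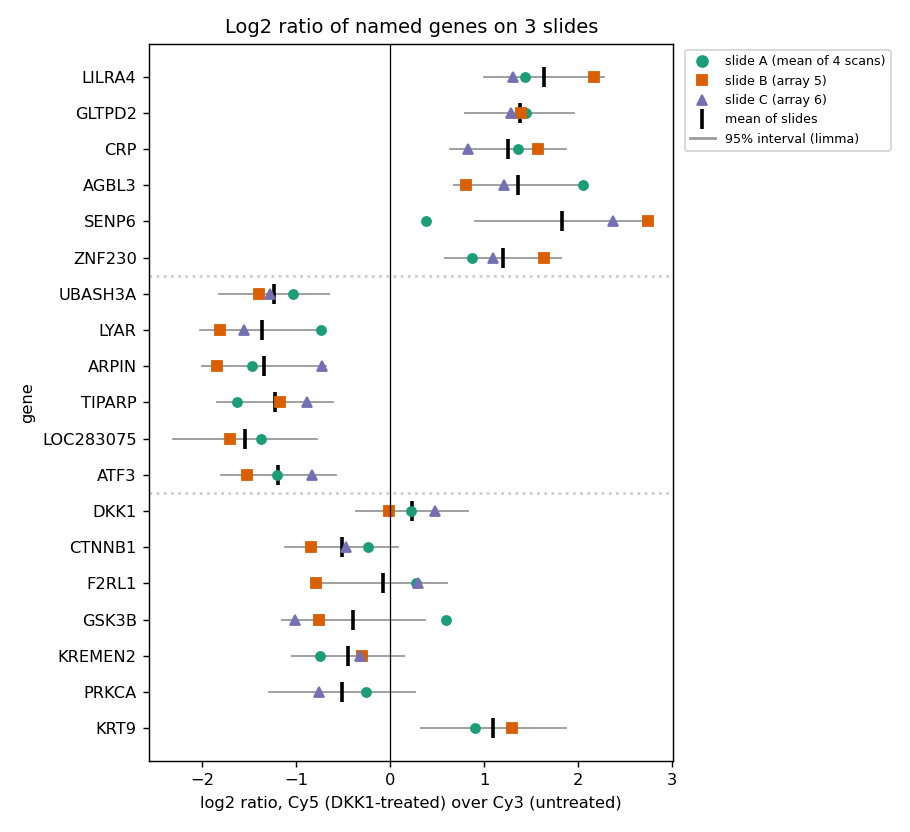
Log2 ratio of Cy5 (DKK1-treated) over Cy3 (untreated) on the horizontal axis for the 12 genes of smallest p (upper rows) and the study's own genes (lower rows), 1 gene per row. Symbols are single slides, black ticks their mean and grey lines the 95% interval from limma; KRT9 has symbols at 0.90 and 1.30, while GSK3B lies at 0.60 on slide A and at -0.76 and -1.02 on slides B and C.

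Genes that the study is known to have discussed were read first as a list, and as they were chosen on these cells they are not independent evidence of a direction. KRT9, the keratin of palm and sole epidermis (hgB36, chromosome 17, 36975621 to 36981836), had a log2 ratio of 1.10 ± 0.28 (SD, n = 2 slides; 95% interval 0.33 to 1.87). It was above 0 on both slides measured, had no value on array 6, and did not pass (limma adjusted p = 0.376). CTNNB1, which encodes beta-catenin (chromosome 3, 41215945 to 41256943), was at -0.52 ± 0.31 (95% interval -1.12 to 0.09) and below 0 on 3 of 3 slides with array 6 as labelled, with an adjusted p of 0.423. GSK3B, the kinase that marks beta-catenin for degradation (chromosome 3, 121027372 to 121296280), was at -0.39 ± 0.87, with slide A above 0 and slides B and C below, and at 0.28 with array 6 turned, -0.21 without array 5 and -0.08 without array 6. F2RL1, the receptor PAR2 (chromosome 5, 76150609 to 76167319), was at -0.07 ± 0.62, and at 0.06 without centring of the arrays, 0.05 with array weights, 0.28 without array 5 and -0.26 without array 6. DKK1 itself was at 0.23 ± 0.25, or -0.09 with array 6 turned, 0.35 without array 5 and 0.10 without array 6, and its receptor KREMEN2 at -0.45 ± 0.25. The 2 PRKCA probes tested, for protein kinase C alpha, gave -0.51 (0.25 with array 6 turned) and 0.75, each on 2 slides. KLHL20, a kelch-like protein, had a value on array 6 alone (0.23). LRP6 and the single probes of PRKCB were measured on too few arrays or slides to be tested. Of the 7 listed genes tested, 2 had values above 0 and 5 below, and 0 passed over all probes or adjusted over the list alone. Camera took only the 5 measured on 3 slides (adjusted p = 0.641). Adjusted over the list alone, KRT9 passed without array 1 (0.047), without array 3 (0.038) and with the mean of all probes of a gene (smallest p 0.041), where PRKCB was tested and passed as well. For KRT9 the scans of slide A gave 0.45, 2.07, 0.12 and 0.95 on arrays 1 to 4. Leaving out array 1 or 3 thus drops a low scan and no slide. Its mean rank of signal lay at 24.1% of probes.

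Of 17 known targets of Wnt signalling 10 had values above 0 and 7 below, none passed, and the list median was 0.12 (camera adjusted p = 0.847). JUN was at -0.84 ± 0.36 and CCN4 (WISP1) at 0.71 ± 0.48, or -0.44 and 0.44 with array 6 turned, and CCN4 at 0.44 without array 5. Of 38 components of the pathway 22 had values above 0 and 16 below (median 0.06, mean -0.02, camera adjusted p = 0.967; median -0.13 with array 6 turned). Its members of smallest p were the receptor ROR2 (-0.87 ± 0.18, n = 2 slides, or -0.12 with array 6 turned) and the ligand WNT10A (-0.77 ± 0.09, n = 2 slides, or 0.06 with array 6 turned). Notch pathway genes stood at 6 above and 12 below 0 (median -0.042, or 0.0030 with an equal spread of the arrays), with LFNG at -0.95 ± 0.21 and NOTCH1 at 0.69 ± 0.59 (0.15 and -0.03 with array 6 turned; camera adjusted p = 0.847). TGF-beta targets and matrix genes stood at 12 above and 10 below (median 0.09, or -0.08 with array 6 turned and -0.0081 after median centring), with the receptor TGFBR2 at -0.77 ± 0.18 and TGFB1 at -0.56 ± 0.14 (adjusted p = 0.847).

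Among keratinocyte genes, 12 of 16 markers of the basal layer had values below 0 and the list median was -0.42 (camera adjusted p = 0.105, and adjusted p = 0.982 with an estimated correlation). EGFR, the epidermal growth factor receptor, was at -0.69 ± 0.39. Of 29 differentiation genes 17 had values below 0 (median -0.17, adjusted p = 0.779). KRT10, the keratin of the suprabasal layers, was at -0.84 ± 0.14 (-0.28 with array 6 turned), and the transglutaminase TGM3 at 0.91 ± 0.03 on 2 slides, with the scans of slide A between -0.48 and 2.83. Without array 1 TGM3 was at 0.60, and it was at -0.41 after median centring and -0.46 without centring. Wound and palm or sole keratins were split evenly at 5 and 5, with KRT4 at -0.78 ± 0.52 beside KRT9 (adjusted p = 0.847). Of 21 adherens junction and desmosome genes 12 lay below 0, with the adhesion molecule NECTIN1 at -1.06 ± 0.71 and the plakophilin PKP1 at 0.65 ± 0.15 (adjusted p = 0.835). Of 8 protein kinase C genes 5 lay above 0, with PRKCZ at -0.38 ± 0.04, and that list had too few genes on 3 slides for the list test. In the list of signals between keratinocytes and melanocytes 5 of 10 lay above 0, with PTGS2 at 0.52 ± 0.04 and FGF7 at 0.85 ± 0.99 (adjusted p = 0.779).

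Immediate-early genes, which respond to stimuli within the first hours, were the only list with members past the threshold adjusted over the list alone. Over all probes 0 of its 26 genes passed, and adjusted over the list alone 2 did, ATF3 and CCN1 (-1.04 ± 0.35, n = 3 slides), the smaller p being 0.037 in limma. Both were below 0 on 3 of 3 slides with array 6 as labelled. Each list was adjusted separately, with no correction for the number of lists. A pass in 1 list can therefore arise by chance. Over 18 other settings at least 1 gene of the immediate-early list passed in 10, with smallest p from 0.011 to 0.346. Those 10 include the settings without array 1, 2, 3 or 4, each of which drops a scan of slide A and no slide. Neither ATF3 nor CCN1 passed where a slide was dropped, without array 5 (0.134) or array 6 (0.071). The same held with array 6 turned (0.173), after median centring (0.078) and without centring (0.208). The list as a whole had 12 values above and 14 below 0 (median -0.042, camera adjusted p = 0.277; median 0.0081 without centring). Heat-shock and chaperone genes included DNAJA1 (-1.07 ± 0.49) and DNAJB1 (-0.86 ± 0.36), with 11 of 19 below 0 (adjusted p = 0.641). The unfolded protein response held XBP1 (-1.13 ± 0.83; -0.66 without array 5) and HSPA5 (0.42 ± 0.27; 0.03 with array 6 turned), with 6 of 10 below 0 (adjusted p = 0.835). NF-kappaB and inflammatory genes included IL36G (0.72 ± 0.34) and SERPINB2 (-0.64 ± 0.33), with 13 of 20 below 0 (median -0.0034, or 0.12 without centring; adjusted p = 0.847), and the interferon list IFI44L (-0.68 ± 0.74; -0.32 without array 5 and -1.06 without array 6) and IFITM2 (0.55 ± 0.19), with 9 of 15 above (median 0.13, or -0.10 after median centring; adjusted p = 0.847). Among p53 and apoptosis genes 11 of 17 lay above 0 (median 0.23, or -0.0024 with array 6 turned), although CASP9 (-1.32 ± 0.34, n = 2 slides; 0.24 with array 6 turned) and TP53I3 (-0.89 ± 0.19) lay below (adjusted p = 0.779).

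Of 34 oxidative phosphorylation genes 25 had values below 0 (median -0.17, camera adjusted p = 0.105), with UQCRQ at -0.90 ± 0.28 and ATP5F1C at -0.84 ± 0.57. Of 56 ribosomal protein genes 36 lay below 0 (median -0.14, adjusted p = 0.138), with RPL41 at -1.21 ± 0.44 and RPSA at -0.54 ± 0.49, or -0.34 without array 6. Of 23 proteasome genes 13 lay below 0 (median -0.08, adjusted p = 0.138), with PSMC1 at -1.08 ± 0.61 and PSMA6 at -0.82 ± 0.38. ATP5F1C, RPSA and PSMC1 changed sign with array 6 turned, and the proteasome median became 0.0072. The medians of the basal, oxidative phosphorylation and ribosomal lists were below 0 under each of the 3 scaling alternatives and with array 6 turned, where the ribosomal one was -0.023. This was not particular to them. It also held for the differentiation, adherens junction and desmosome, heat-shock and unfolded protein response lists and the study's own genes. Medians of the Wnt target, cell cycle and keratinocyte to melanocyte lists stayed above 0 in the same settings. Cell cycle genes were split at 11 and 11, with TYMS at -0.61 ± 0.33 and CDC20 at -0.58 ± 0.46, or -0.33 without array 5 (adjusted p = 0.967). Cholesterol synthesis genes had 12 of 21 above 0 (median 0.06, or -0.06 with array 6 turned and -0.08 after median centring), with the regulator SREBF1 at -0.78 ± 0.36 and SCD at -0.63 ± 0.53, or -0.33 without array 5 (adjusted p = 0.847). The housekeeping list stood at 7 above and 10 below (median -0.033, or 0.08 with array 6 turned and 0.0088 without centring), with POLR2A, the largest subunit of RNA polymerase II, at 0.55 ± 0.27 (adjusted p = 0.847).

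Markers of other cell types were few. Of 13 fibroblast genes 6 lay above 0, with LOX at -0.99 ± 0.43 on 2 slides and POSTN at 0.53 ± 0.85 (camera adjusted p = 0.847). With array 6 turned POSTN was at -0.47 and the list median went from 0.10 to -0.099, and without array 6 POSTN was at 0.046. The melanocyte list had 1 gene tested, MITF (-0.68 ± 1.10), whose lowest channel signal of 1, on slide B, leaves its size unknown, and the immune and Langerhans cell list 1, HLA-DPB1 (-0.52 ± 0.14). The endothelial list had 5 tested, among them ESAM (0.64 ± 0.17) and PECAM1 (-0.83 ± 0.35, n = 2 slides). None passed over all probes or adjusted over the list alone. With the settings reported here the same held for each list but the immediate-early one, although members of other lists passed over their list alone under some alternatives.

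**Figure D3:**
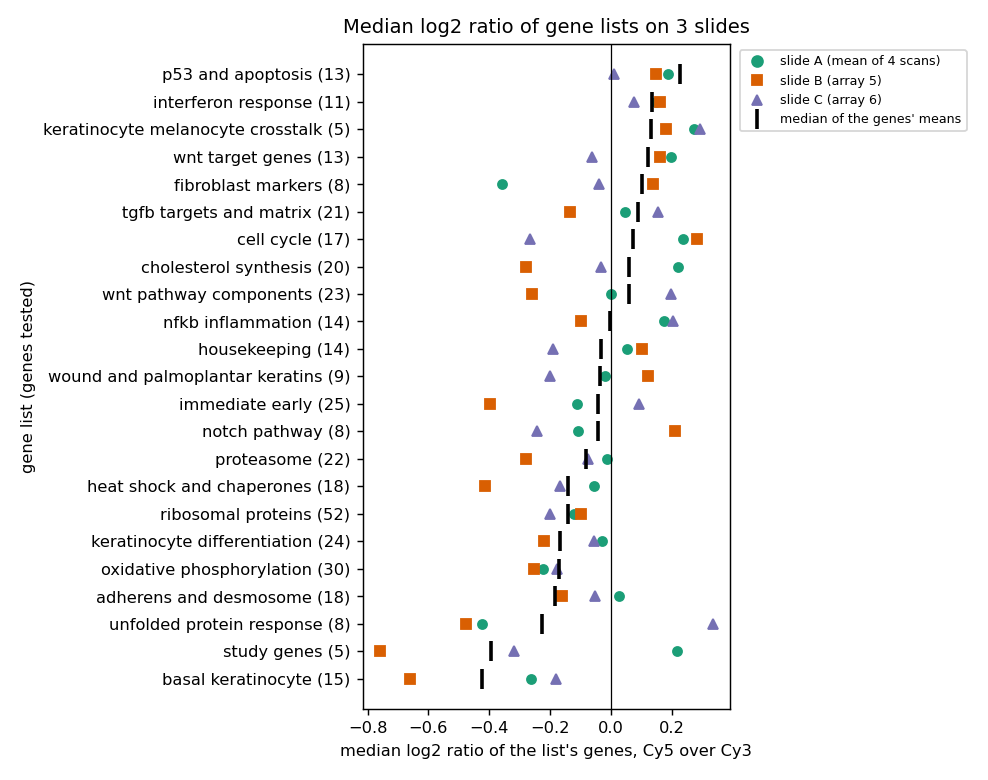
Median log2 ratio (Cy5 over Cy3, horizontal axis) of the genes of each list measured on 3 slides, 1 list per row with its number of genes in brackets. Symbols are slides and black ticks the median of the genes' means. The medians ran from -0.42 (basal keratinocyte) to 0.23 (p53 and apoptosis). In 9 of the 23 lists all 3 slides lay on one side of 0, while 39.8% of single probes did, against 25% by chance.

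Of the 27 lists fixed in advance 23 could be tested, and 0 were shifted at an adjusted p under 0.05 in camera, with 4 at an unadjusted p under 0.05. With an estimated correlation 0 lists passed and the smallest adjusted p was 0.982, and fry gave 0 with a smallest adjusted p of 0.379. The median and the test differed in sign for 4 lists (Wnt pathway components, cell cycle, NF-kappaB and cholesterol synthesis). With array 6 turned the list medians ran from -0.29 (basal keratinocyte) to 0.19 (cell cycle), and all 3 slides lay on one side of 0 in 6 lists against 9. Among single probes on 3 slides that share was 39.8% as labelled and 25.8% with array 6 turned. These counts therefore do not set the lists apart from single probes. Between slides the log2 ratios correlated across probes at r = 0.239 (A and B), 0.139 (A and C) and 0.232 (B and C), with Spearman's rho of 0.321, 0.202 and 0.201.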

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

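All tests of explanations in this part, and the limits that decide them, were chosen after the result was seen, except the sign assignments, which were fixed before the data were examined for the 6 arrays and later applied to the 3 slides.

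Negative-control wells of random sequence carried signal. The number of such wells brighter than the median gene probe was 36 of 118 on array 1, 37 of 122 on array 2, 37 of 118 on array 3, 43 of 123 on array 4 and 59 of 135 on array 5. These counts are over control wells with a value, out of 182 on each array. Array 6 stood apart, with only 47 such wells and 2.13% of them above that median, against 30.3% to 43.7% on the others. This gap was 1 past the limit among 8 measures tried over 6 arrays, and chance gives such a gap in about 1 in 20 groups. The limit takes the arrays as independent, which scans of one slide, as arrays 1 to 4 were counted, are not, and 3 slides are too few for it.

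The log2 ratios of Cy5 over Cy3 were shared between slides, with a mean r of 0.203 across probes after loess. A brightness trend of the dyes argues poorly as the whole cause, since the mean r was 0.146 with median centring alone and 0.203 after loess. A dye effect of single probes and a response to DKK1 cannot be told apart, because no settled dye swap exists. Control wells, which should hold no human target, also leaned to Cy5 on every array (lowest median log2 ratio 0.449), although their ratios correlated at r = -0.235 between slides A and B, -0.165 between A and C and 0.360 between B and C, and with array 6 turned as the header marks it the mean r was -0.044. With 3 slides there are 4 sign assignments, too few for a share under 0.05 (0 calls as labelled, highest other 4; 1127 probes at an unadjusted p under 0.05 against at most 391).

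Entering the 6 arrays as separate replicates called 2063 probes higher and 2334 lower in limma, ATF3, CCN1 and KRT9 among them. Scans of one slide counted as replicates are a candidate explanation, since with the slide as a random block 0 probes passed (correlation within slides 0.872). Only 4 of the 32 sign assignments turn the scans of slide A together, too few for a share under 0.05: the labelled one gave 4397 calls, 1 of 4 as large, and the highest other 2509. No biological explanation was tested for this pattern.

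Log2 signals of slide A correlated at r = 0.428 with slide B and 0.319 with slide C, against 0.629 between B and C. A shift of all wells by a fixed number is argued against, since r between slide A and the other slides was 0.402 without a shift and at most 0.124 at any other shift of up to 400 wells. Uneven spots on slide A are a possible explanation. Wells listed for one oligonucleotide had a median SD of 1.74 on the log2 scale there, against 0.53 on slide B and 0.59 on slide C. Of 10 repeated oligonucleotides 8 spread more on slide A than on both others. Other oligonucleotides in some of those wells could widen this SD too, so it does not tell the 2 explanations apart. Other oligonucleotides in some wells stay open as well, since 2 of 13 repeated oligonucleotides, both for ACTB, were measured in most wells of one side and few or none of the other. No biological explanation was tested, as all slides carry the same group.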

How the results depend on the processing

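The fit of 6 separate arrays was the one set before the data were examined; averaging arrays 1 to 4 in its place, turning array 6 alone, the slide as a block, median centring for the correlation and the list test over all probes were chosen after seeing the data. The deposited ratios, which hold array 6 turned, were set before. Counts of 0 higher and 0 lower probes were also found with array 6 turned, with the slide as a block and under the other alternatives run, except the following. The deposited ratios, with array 6 turned as deposited, gave 4 higher and 15 lower probes. In 17 of those 19 the largest slide exceeded the next by over 3 times, and 14 had a channel signal of at most 10 (73.7%, against 3.72% of all probes tested); the 4 higher were TCF15, DGKH, PPP3CB and TMEM187, named after their values were seen. Leaving out 1 replicate gave 0 to 1 higher probes (ADH6, without replicate 5, where 2 slides remain) and 0 lower. Arrays 1 to 4 as separate replicates gave 2063 and 2334, and with array 6 turned as well 1057 and 1452. No list was shifted under any alternative run, the smallest adjusted p being 0.055 after median centring. The mean correlation between slides of 0.203 became 0.146 after median centring and 0.146 with no centring, and -0.044 with array 6 turned; the cause was not tested. Without centring the counts at an unadjusted p under 0.05 were 342 higher and 253 lower, against 433 and 694. Leaving aside the fit of 6 separate arrays, 50 of the 66 genes chosen by the naming rule kept their sign under every other alternative fixed before the data were examined in which they were measured. Under these alternatives 1, MITF, passed (-4.00 with the deposited ratios, set by slide B at -9.94 with a channel signal of 1). Filters on dim or missing probes and the variance trend cannot change a mean. Leaving out 1 of arrays 1 to 4 changes only the mean of slide A. A kept sign there says little. Of the genes chosen by the naming rule 8 of 61 without array 5, and 7 of 57 without array 6, moved by over 1.5 times. With arrays 1 to 4 separate, the fit set before the data were examined, 57 of the 66 passed. Adjusted over the list alone, members of 14 of the 26 lists other than the immediate-early one passed under at least 1 of 18 alternatives (arrays 1 to 4 not separated), among them CASP9 after median centring (0.035) and, with that same signal of 1, MITF without centring (0.026). Normexp was not run. Signal over background limits the dim end: on array 1 571 wells had a channel signal of at most 10. No paired analysis was possible because the series has 1 group of ratios, each already pairing treated with untreated RNA.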

Other observations

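DKK1 blocks Wnt signalling, and a hypothesis was that Wnt target genes lie lower within 2 h. The list and its camera test were fixed before the data were examined, while the hypothesis was written after the list's values were seen. The mean log2 ratio of the 13 target genes on 3 slides was 0.07 ± 0.09 (SD, n = 3 slides), and the list was not shifted (camera adjusted p = 0.847). The slide means were 0.09, 0.15 and -0.04. With 3 slides a small change in either direction is not excluded.

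Both oligonucleotides for ACTB were printed in 17 wells. H200021335 had values in 17 wells of array 3, in 0 of array 5 and in 3 of array 6, while H200009216 had values in 0 wells of array 3, 15 of array 5 and 17 of array 6. GAPDH wells (H200007830) had an SD of 1.89 on the log2 scale on array 3, 0.77 on array 5 and 0.046 on array 6, which had 287 wells with a channel at 60000 or more. PRKCB, which the study discussed, had a log2 ratio of 2.04 on slide A and 1.62 on slide B for one probe (H200006363), measured on 3 arrays and so below the minimum for the test. A second probe (H200020472) was at 0.54 on slide A, from 0.08 to 0.90 over its 4 scans, and had no value on slides B and C. With a minimum of 2 arrays the first probe passed adjusted over the study's own list alone (limma adjusted p = 0.0082), which is not independent evidence.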
